A study of Homo sapiens with 4 samples.

How the data were processed

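The series holds polyadenylated RNA from HEK293 cells, with 2 WT libraries and 2 libraries of a HEMK1 KO clone. Per the labels' protocols, the KO was made with a pool of Cas9 plasmids carrying different guides, single cells were sorted and expanded, and libraries were made from 100 ng of total RNA with a low-input kit of NEB. Per the submitters' processing notes, FastQC, Trimmomatic, STAR, HTSeq and DESeq2 were used with the hg38 genome. Their versions, the annotation release, the strand setting and any filters are not given in the sources used here. Whether reads from a gene and an overlapping antisense gene were counted apart is therefore unknown.

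The deposited values are raw counts per gene for each library, as whole numbers with no normalization, counted by the authors with HTSeq per the sheet names. Each table has 78686 features, and 0 of them hold totals or unassigned reads, so the share of reads outside genes is unknown. The authors' deposited comparison table gives, per its header, a base mean (counts divided by size factors, a signal averaged over the 4 libraries), the log2 fold change of KO over WT with its standard error, a Wald score, a p-value and an adjusted p-value. That table holds 78685 genes, of which 12392 have an adjusted p, and it was used only for comparison with the fits made here. Libraries were taken from the sheet names, each of which matched 1 sample title.

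Gene identifiers were matched without their version to a table of gene names, which named 61463 features and 98.3% of counts, and to the GENCODE 29 annotation of GRCh38, which gave type and position for 57288 features. The annotation may differ from the one the authors used, so gene types and coordinates are those of GENCODE 29.

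Counts were filtered with filterByExpr (minimum count 10), scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood fit, genotype as the only term), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. HEMK1 did not pass the filter, so its fold change comes from the same fit without a filter. CPM values were computed from the counts with TMM-scaled library sizes, except that summed CPM of marker lists used unscaled library totals. The TMM factors lay between 0.980 and 1.02, and the common biological coefficient of variation was 0.143. For low counts, ratios are given with 95% exact binomial intervals, and for a group at 0 a bound against a floor of 3 counts over the group; intervals and floors cover counting error only, since the reads carry no molecular identifiers.

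Before the data were examined, 40 gene lists with 1251 symbols were fixed, of which 36 had the minimum of 5 tested members. They were tested with camera in limma 3.58.1 (preset correlation 0.01, prior count 2 in the log2 CPM), as were chromosomes and bins of 20 Mb with at least 20 tested genes. Camera with an estimated correlation and fry were run as alternatives. Lists of the other cell types that a culture could hold were included. Counts adjusted over the list alone used the edgeR p-values of the list's members.

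Genes named in the text follow a rule also fixed before the data were examined: among called genes with a mean of at least 5 CPM, a symbol that is neither clone-type nor pseudogene-type and both KO libraries on the same side of both WT libraries, the 10 largest changes per direction; HEMK1; in each list up to 4 called members or, where none was called, the 1 with the smallest p; called neighbours of HEMK1; and a few fixed genes such as MTRF1, N6AMT1, ATF4, DDIT3, GDF15 and TFAM. Other names were chosen after their values were seen and are marked so.

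Replicates were compared first. The chi-square statistic per degree of freedom was 5.01 between the WT libraries and 5.38 between the KO libraries. No library therefore repeats another within sampling noise, and each counted as 1 replicate. Between groups the statistic was 4.90 and 4.74 for WT replicate 1 against KO replicates 1 and 2, and 7.42 and 7.39 for WT replicate 2. A permutation of 2 against 2 libraries cannot give a two-sided p below 0.333. P-values measure the spread between these libraries of 1 clone and 1 WT population.

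The tests were run on simulated counts for the 10670 tested genes of the KO against WT comparison with 200 changed genes. edgeR recovered 3.03% of 1.5-fold, 41.5% of 2-fold and 87.3% of 4-fold changes, with 3 false calls among 87, so most changes of less than 2-fold are beyond this depth and number of libraries. Camera called a simulated shift of 0.5 in a list of 25 genes (adjusted p = 8.4e-09) with 0 false lists. With an estimated correlation camera did not call the same shift (adjusted p = 0.701). A call lost in that setting therefore cannot by itself decide whether a set changed. Simulated genes were drawn independently, so these runs do not show how the preset correlation performs where members vary together. In the data the estimated correlation was 0.616 for the mRNAs of mitochondrial DNA and 0.668 for cytosolic ribosomal protein genes.

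Parents of processed pseudogenes were found with blastn 2.17.0, taking hits over at least 50% of the pseudogene. Alternatives were other scalings, other count filters, DESeq2 1.42.0, limma-voom, a fold threshold of 1.5 in glmTreat, the replicate number as a block, removal of each library in turn, and removal of genes of mitochondrial DNA. Removal of pseudogenes and of a loess trend on GC content and length was added after seeing the data.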

Results

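RNA was sequenced from HEK293 cells, an aneuploid human line derived from embryonic kidney, as 2 wild-type (WT) libraries and 2 libraries of HEMK1 knockout (KO) cells. HEMK1 is a methyltransferase that modifies release factors of mitochondrial translation, and the comparison asked which transcripts differ when the gene is edited. The KO libraries came from 1 clone expanded from a single Cas9-edited cell, so loss of HEMK1 and other differences of that clone from the WT cells are the same contrast. The labels speak of 2 biological replicates. Total gene counts were 2476471 and 2671594 in the WT libraries and 2856784 and 3202039 in the KO libraries, and between 20530 and 21639 genes had at least 1 count per library. The 2 WT libraries correlated with each other at r = 0.973 and the 2 KO libraries at r = 0.974 in log2 CPM (counts scaled by library total) across genes, which are not independent replicates, against 0.963 to 0.967 between groups.

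HEMK1 (ENSG00000114735.10, chromosome 3, positions 50569152 to 50596168 of GRCh38) was close to the limit of detection. It had 6 and 9 counts in the WT libraries and 1 and 7 counts in the KO libraries. The ratio of KO to WT was 0.455, with a 95% exact counting interval of 0.167 to 1.14, and the log2 fold change was −1.11 ± 0.79 (SE, n = 2 per group; adjusted p = 0.830 by edgeR). A difference in HEMK1 mRNA was therefore not detectable at this depth, and the counts do not check the labels. Of the genes around HEMK1 on chromosome 3, 5 were tested, none was called over all genes and 0 were called when adjusted over the list alone, with a median log2 fold change of 0.14. Their smallest p belonged to GNAI2, a G protein subunit, at 0.67 ± 0.53 (SE; edgeR adjusted p = 0.792).

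Few genes were called between the KO clone and WT cells, and among protein-coding genes taken by the rule for named genes IGF2R fell and DDR2 rose the most. IGF2R, the receptor that carries mannose 6-phosphate-tagged enzymes to lysosomes and clears IGF2, fell from 298 ± 177 CPM to 9.10 ± 2.39 CPM (SD, n = 2 per group), a log2 fold change of −5.03 ± 0.50 (SE; adjusted p = 0.0102 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). DDR2, a receptor tyrosine kinase for fibrillar collagen, rose from 8.42 ± 4.54 CPM to 66.2 ± 4.33 CPM, a 7.94-fold increase (adjusted p = 0.00250). LDHB, the lactate dehydrogenase subunit that favours pyruvate formation, fell from 216 ± 20.5 CPM to 91.9 ± 4.44 CPM (log2 fold change −1.23; adjusted p = 0.00426). SRSF5, a splicing factor of the SR family, rose from 289 ± 51.8 CPM to 569 ± 15 CPM (log2 fold change 0.98; adjusted p = 0.0163).

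Of 10670 genes tested with edgeR, 5 were higher and 30 were lower in KO libraries at an adjusted p under 0.05. Of the 30 lower genes, 20 were pseudogenes by type or name. At an unadjusted p under 0.05 there were 436 higher and 464 lower genes, 900 against 534 expected by chance. The 5 higher genes were DDR2, SRSF5, the long non-coding RNAs LINC01234 (log2 fold change 2.21 ± 0.24, SE) and LINC01036, and TAF11L11 (1.77 ± 0.23), a member of a multicopy family of TAF11-like genes whose reads may be shared between copies. LINC01036 had 1 count over the WT libraries and 58 over the KO libraries, a ratio of 49.5 with a 95% counting interval of 8.53 to 1987. Lower genes with a symbol included FHL1, a LIM-domain protein of muscle and cytoskeleton (−1.97 ± 0.21), SOX11, a transcription factor of neural progenitors (−1.78 ± 0.25), NF2, which encodes the tumour suppressor merlin (−1.19 ± 0.20), and the non-coding LINC00115 (−3.57 ± 0.56). BCHE, which encodes butyrylcholinesterase, had 45 counts in WT and 0 in KO libraries, at least 17.6-fold lower against a floor of 3 counts over the group. AC010761.2, annotated as antisense to NEK8, had 78 and 2 counts, a ratio of 0.0219 with an interval of 0.00260 to 0.0817 for counting error only; with the strand setting unknown, these counts could include reads of NEK8. The other 2 lower genes that are not pseudogenes, ENSG00000309483.1 (−2.91 ± 0.33) and ENSG00000293331.2 (−1.22 ± 0.19), had no symbol. BCHE, LINC01036, AC010761.2 and these 2 lay outside the rule for named genes and were chosen after their values were seen. Counts of calls depended on each library, with 4 higher and 3 lower genes without WT replicate 1, 1 and 13 without WT replicate 2, 18 and 80 without KO replicate 1, and 25 and 164 without KO replicate 2. LINC01234, TAF11L11, LINC00115, FHL1, SOX11, LDHB and NF2 missed the threshold without WT replicate 1 (edgeR adjusted p of 0.101 to 0.228) at log2 fold changes of 2.37, 1.89, −3.96, −1.83, −2.01, −1.13 and −1.19 in that order. So did LINC01234, TAF11L11, SRSF5, LINC00115, SOX11 and NF2 without WT replicate 2, at 2.03, 1.62, 0.77, −3.05, −1.54 and −1.22. IGF2R missed it without KO replicate 1, at −5.35. The direction could hardly change, since the rule for named genes required both KO libraries on the same side of both WT libraries.

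**Figure D1:**
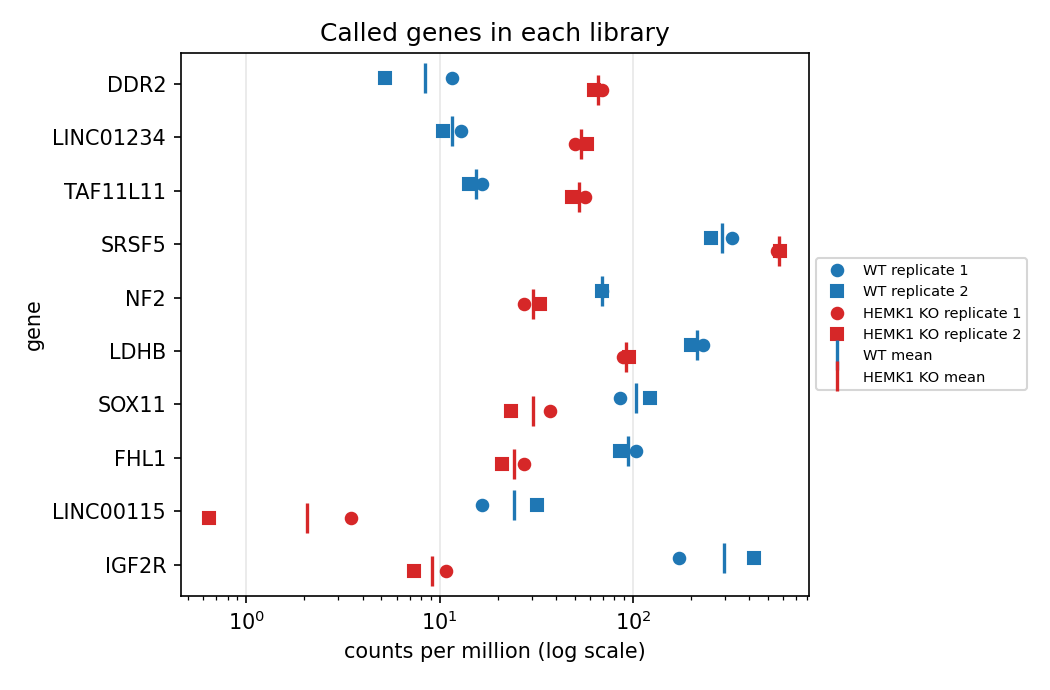
CPM (horizontal, log scale) of the 10 called genes that the rule for named genes took by size of change, in each of the 4 libraries, with group means as vertical bars. The KO libraries lie on one side of both WT libraries for each gene because the rule required it. IGF2R spans 173 to 422 CPM in the WT libraries against 7.41 to 10.8 CPM in the KO libraries.

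Processed pseudogenes, which are intronless copies of mRNAs, were lower in KO libraries as a class. The 441 tested had a median log2 fold change of −0.52 (quartiles −0.89 and −0.23), against 0.02 for 8483 protein-coding genes, and 125 of them were lower and 5 higher at an unadjusted p under 0.05. Of these 441, edgeR called 18 as lower. With MTCO3P12, an unprocessed pseudogene, and RPS27AP5, a pseudogene by name that GENCODE 29 types as protein-coding, 20 pseudogenes were called by type or name. The 20 called became 2 without WT replicate 1, 9 without WT replicate 2, 45 without KO replicate 1 and 74 without KO replicate 2. Pseudogenes named after ribosomal protein genes made up 14 of the 20, among them RPL37P2 (−2.48 ± 0.27, SE), RPL17P18 (−2.31 ± 0.26) and RPS23P8 (−1.32 ± 0.18). A further pair without such a name, AL031727.1 and AC034236.1, matched the ribosomal protein genes RPS14 (95.1% identity) and RPS25 (99.3%). In 5 called pseudogenes no read was counted in either KO library, and the most abundant of these was AL512646.1 on chromosome 9 (positions 104328320 to 104329396), with 553 counts in WT and 0 in KO libraries, at least 216-fold lower. MTCO3P12, a nuclear copy of mitochondrial DNA on chromosome 1, was also lower (−0.92 ± 0.16). These pseudogenes were named after their values were seen. Reads of such copies can be split with near-identical parent genes, so their levels are uncertain. Of the 441, 342 had a tested parent among coding genes, and AL512646.1 and RPL17P18 did not. Sharing of reads with a parent was therefore not examined for AL512646.1 and RPL17P18. The 2 WT libraries also differed in this class, with a median log2 ratio of WT replicate 2 to WT replicate 1 of −0.51, against −0.34 and −0.09 for KO replicates 1 and 2 to WT replicate 2. Pseudogenes took 1.78% and 1.26% of counts in the WT libraries and 1.00% and 1.04% in the KO libraries (exact two-sided permutation p = 0.333, the smallest that 2 against 2 libraries allow).

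**Figure D2:**
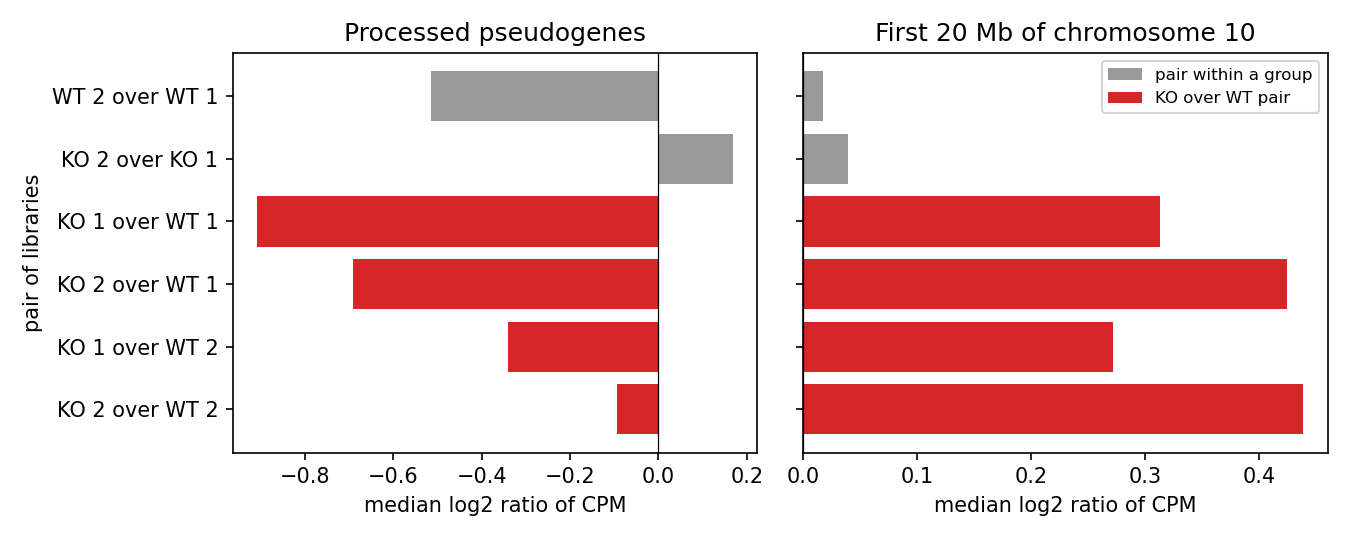
Median log2 ratio of CPM (horizontal) for each pair of libraries, over 441 processed pseudogenes (left) and over 61 genes of the first 20 Mb of chromosome 10 (right). Grey bars compare libraries within a group and red bars compare KO with WT. On the left the pair of WT libraries differs by −0.51, and on the right the pairs within a group differ by 0.02 and 0.04 while the KO over WT pairs lie between 0.27 and 0.44.

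The mRNAs encoded by mitochondrial DNA were lower on average in KO libraries, although no single mRNA passed the test over all genes. Of the 13, which encode subunits of the respiratory chain and ATP synthase, 12 had a log2 fold change below 0, with a median of −0.34, and 0 were called over all genes or when adjusted over the list alone. MT-CO2, with the smallest p, had 5888 ± 568 CPM in WT and 4182 ± 439 CPM in KO libraries (SD, n = 2 per group), a log2 fold change of −0.49 ± 0.17 (SE; edgeR adjusted p = 0.406). MT-CO1 had −0.88 ± 0.29, and MT-ND3 was the exception above 0 at 0.30 ± 0.26. MT-ATP8 overlaps MT-ATP6 and MT-ND4L overlaps MT-ND4 on the mitochondrial genome, so their counts are less certain. The list was called by camera with its preset correlation (adjusted p = 0.0472) and not with an estimated correlation (adjusted p = 0.881). The estimate for this list was 0.616 against the preset 0.01. The call therefore rests on treating mRNAs that varied together as nearly independent. Its mean difference in log2 CPM of −0.35 became −0.21 without WT replicate 2 and −0.15 without KO replicate 2. This mean was further from 0 without either first replicate, reaching −0.56 without KO replicate 1. The share of counts from these mRNAs was 2.50% and 3.67% in the WT libraries and 2.50% and 1.88% in the KO libraries (exact two-sided permutation p = 0.667).

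**Figure D3:**
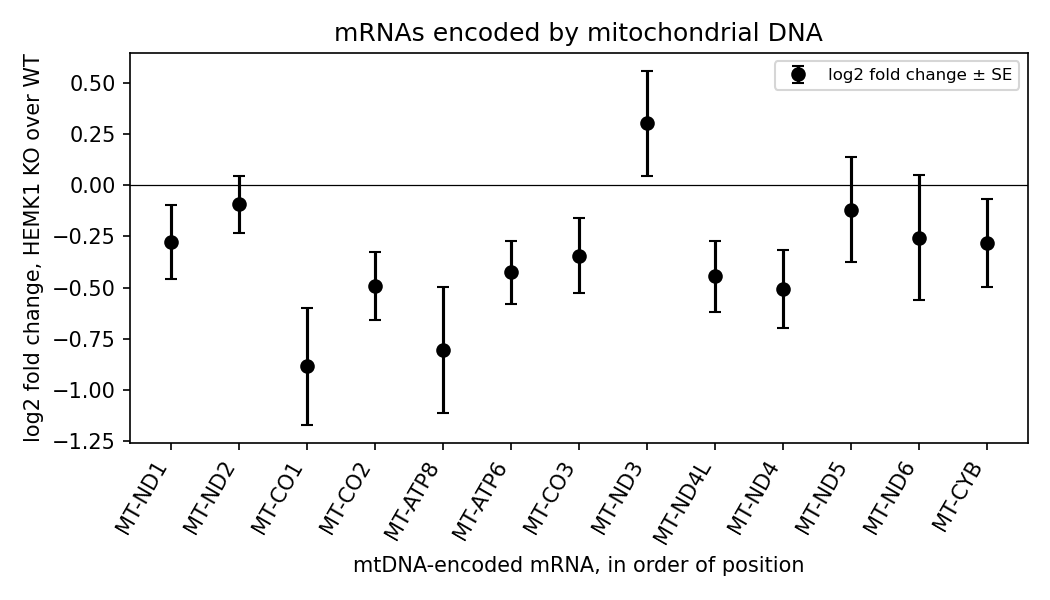
Log2 fold change of KO over WT (vertical) for the 13 mRNAs encoded by mitochondrial DNA in order of position, with bars of 1 SE from the edgeR fit of 2 libraries per group. All but MT-ND3 lie below 0, from −0.88 for MT-CO1 to −0.09 for MT-ND2.

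Nuclear genes for mitochondrial function showed no called difference as groups. Among complex I subunits 30 were tested with a median log2 fold change of −0.10, among complex II, III and IV subunits and cytochrome c 25 with −0.03, and among assembly factors of oxidative phosphorylation 39 with 0.00183, and 0 members of these lists were called over all genes or when adjusted over the list alone. For 18 ATP synthase subunits the median was −0.06, and 2 were lower when adjusted over the list alone and 0 over all genes: ATP5PO (−0.60 ± 0.15, SE; list-alone edgeR adjusted p = 0.0277) and ATP5MF (−0.48 ± 0.14). The 63 mitoribosomal proteins had a median of 0.00886, with 33 above 0, and the 16 mitochondrial tRNA synthetases one of −0.11, and neither list had a call of either kind. Release and rescue factors and their methyltransferases, the proteins nearest to HEMK1 in function, gave 22 tested genes with a median of −0.07 and 0 calls of either kind. In that list MTRF1 had 0.47 ± 0.28, MTRF1L 0.21 ± 0.28, MTRFR −0.18 ± 0.19, and N6AMT1, the methyltransferase of the cytosolic release factor, −1.14 ± 0.57. Regulators of mitochondrial biogenesis (24 tested, median 0.04), mitophagy and mitochondrial dynamics genes (21, 0.07), fatty acid oxidation genes (19, 0.11) and enzymes of the TCA cycle and pyruvate entry (30, −0.05) had 0 calls of either kind, and TFAM, which packages mitochondrial DNA, was at 0.03 ± 0.19. Among 25 mitochondrial chaperones and proteases the median was −0.07, 0 were called over all genes, and PMPCA, a subunit of the presequence peptidase, was lower when adjusted over the list alone (−1.09 ± 0.25; list-alone edgeR adjusted p = 0.0263).

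Stress responses gave no shift of their lists. The list of the integrated stress response (34 tested) had a median log2 fold change of −0.04, and its 1 higher member, over all genes and over the list alone, was DDR2, a collagen receptor that is not an established target and was listed in error. Its other members had edgeR adjusted p of 0.542 or more. ATF4, the transcription factor of that response, had 0.53 ± 0.30 (SE; edgeR adjusted p = 0.679), and DDIT3, which it induces, 0.09 ± 0.36. GDF15 had 1 count over all 4 libraries, too few for a comparison. Lists of the unfolded protein response of the endoplasmic reticulum (20 tested, median 0.02), heat shock (14, 0.02), NRF2 targets (29, 0.11), hypoxia (18, 0.01), p53 targets (18, −0.00534) and apoptosis regulators (16, −0.04) had 0 calls of either kind. In glycolysis 17 genes were tested with a median of −0.05, and LDHB was the 1 lower gene over all genes and also when adjusted over the list alone. In cholesterol synthesis (19 tested, median 0.04) 0 genes were called over all genes and 1 was higher when adjusted over the list alone, IDI1, which isomerises isopentenyl diphosphate (0.58 ± 0.13; list-alone edgeR adjusted p = 0.0157). IDI1 lies in the first 20 Mb of chromosome 10, where 61 tested genes had a median log2 fold change of 0.30. Whether the difference in IDI1 belongs to that regional shift or to cholesterol synthesis was not tested.

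Interferon response genes were the other list called by camera, in the direction of higher levels in KO libraries. Of 23 tested, 17 had a log2 fold change above 0, the median was 0.32, and 0 were called over all genes or when adjusted over the list alone (camera adjusted p = 0.0472; adjusted p = 0.881 with an estimated correlation). PARP9, an ADP-ribosyltransferase induced by interferon, had 62.9 ± 12.7 CPM in WT and 88.8 ± 6.50 CPM in KO libraries (SD, n = 2; 0.50 ± 0.19, SE; edgeR adjusted p = 0.472), and B2M, the light chain of MHC class I, had 1308 ± 11.8 and 1632 ± 123 CPM. Markers of blood and immune cells summed to 0 and 0.374 CPM in WT and to 3.15 and 10.9 CPM in KO libraries. In KO replicate 1 these counts were all of the haemoglobin genes HBA1 (1 count), HBA2 (4) and HBB (4). In KO replicate 2 LYZ had 13 counts and HBB 11, and no other marker had more than 2. The list missed the threshold without each of the 4 libraries in turn while its median difference in log2 CPM, 0.31 with all libraries, kept its direction: 0.29 without WT replicate 1 (camera adjusted p = 0.0518), 0.29 without WT replicate 2 (0.100), 0.24 without KO replicate 1 (0.0648) and 0.35 without KO replicate 2 (0.107). Members of a list beyond its gene of smallest p, such as B2M, ATP5MF and MT-CO1, were named after their values were seen.

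Proliferation and lineage lists held single members that differed, in both directions. Of 37 mitosis genes (median −0.05) 0 were called over all genes, while 2 were higher and 3 lower when adjusted over the list alone. The higher pair was MKI67, the proliferation antigen (0.92 ± 0.18, SE; list-alone edgeR adjusted p = 0.0141), and CENPE, and the lower ones were BIRC5, ESPL1 and CENPA. The list passed fry's test for change in either direction (adjusted p = 0.00672) but was not called in 1 direction by camera (0.567). Immediate early genes (9 tested, median −0.03) did likewise (fry adjusted p = 0.0197 in either direction, camera 0.806), with 0 called over all genes and TXNIP and EGR1 higher and JUND lower when adjusted over the list alone. The 73 cytosolic ribosomal protein genes had a median of −0.11, 0 were called over all genes, and RPL26 was lower when adjusted over the list alone (−0.92 ± 0.18; list-alone edgeR adjusted p = 0.0173). That list was not called (camera adjusted p = 0.0920) but passed the threshold without WT replicate 2 (4.3e-07), where the median became −0.33, and without KO replicate 2 (0.00999), where it became −0.20. The median was 0.09 without WT replicate 1 (0.542) and close to 0 without KO replicate 1 (0.870). DNA replication genes (33, 0.10) and MYC targets (25, 0.07) had 0 calls of either kind.

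Among cell type markers, 12 mesenchymal genes had a median log2 fold change of −0.23, 0 were called over all genes, and CD44, a hyaluronan receptor (−1.07 ± 0.24, SE; list-alone edgeR adjusted p = 0.00899), and VIM, the intermediate filament vimentin (−0.57 ± 0.17), were lower when adjusted over the list alone. Of 8 neuronal genes tested the median was 0.29, 0 were called over all genes, and SYT1, a calcium sensor of synaptic vesicles (1.26 ± 0.31), was higher when adjusted over the list alone (list-alone edgeR adjusted p = 0.0120). The neuronal list as a whole was not called (camera adjusted p = 0.0920) but passed without KO replicate 1 (0.0370), where its median difference in log2 CPM was 0.35 against 0.28 with all libraries. Of 4 pluripotency genes tested, too few for camera, SOX11 was the 1 lower gene over all genes and also when adjusted over the list alone. Epithelial adhesion genes (9 tested, median 0.29), extracellular matrix genes (23, 0.00788) and WNT and TGF-beta targets (9, 0.17) had 0 calls of either kind. RNA handling lists, namely 5 replication-dependent histones (−0.18) and 10 nuclear retained or small structured RNAs (−0.15), also had 0 calls of either kind. Of 36 lists tested, 34 had no member called over all genes, and over the list alone 7 members, DDR2 among them, were higher and 11 lower.

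**Figure D4:**
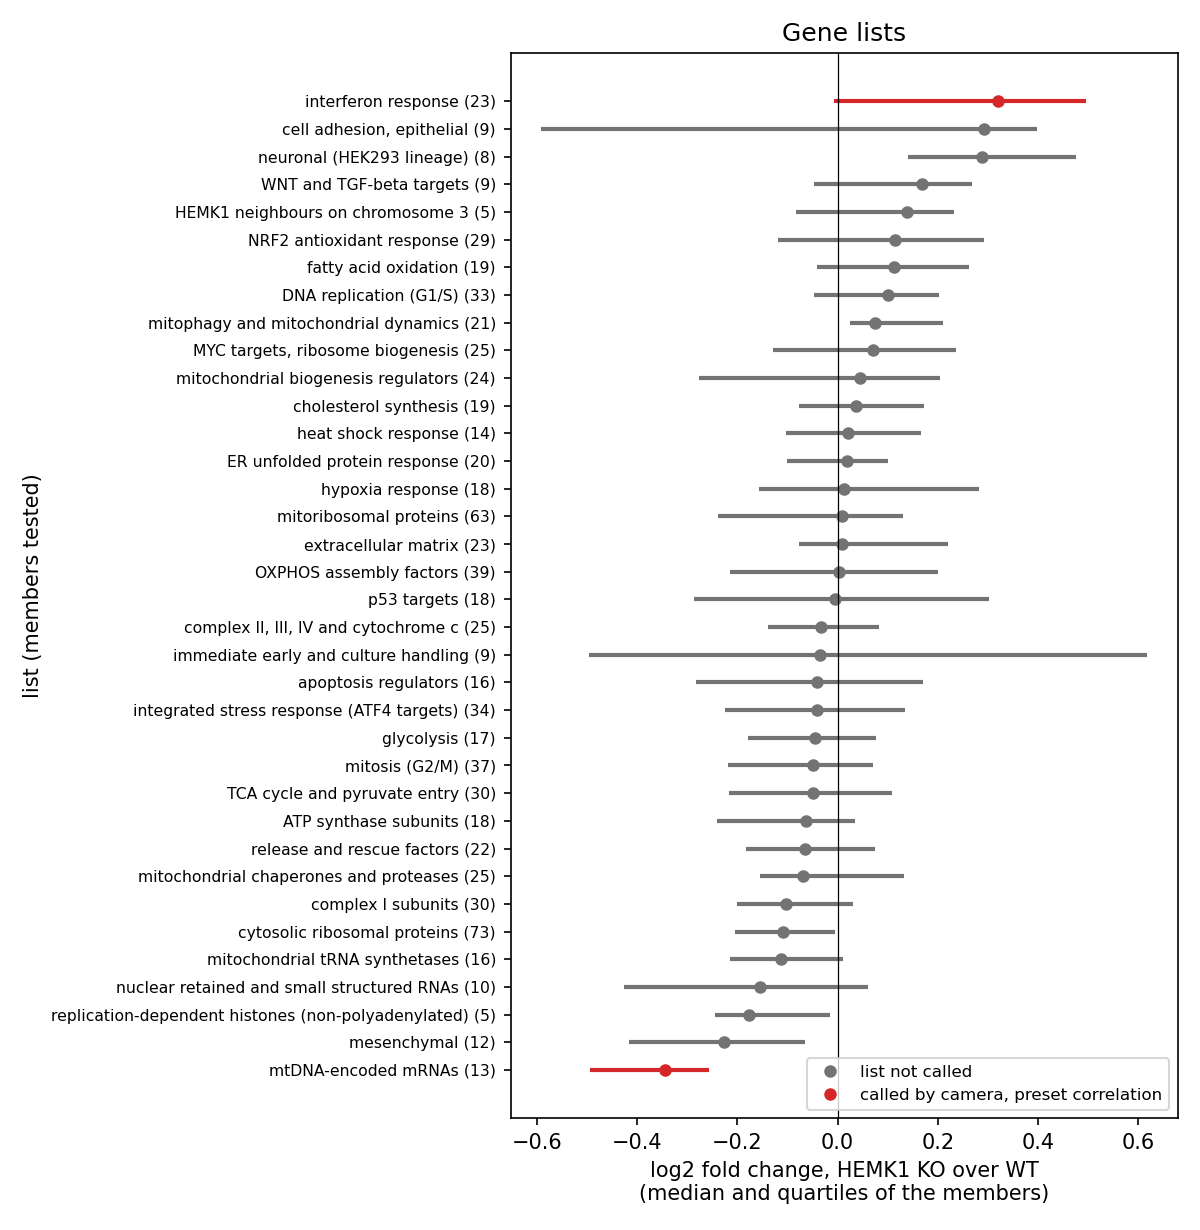
Median log2 fold change of KO over WT (horizontal, points) with quartiles (lines) for the members of 36 gene lists, with the number of tested members beside each name. Red marks the 2 lists called by camera with its preset correlation, mRNAs encoded by mitochondrial DNA at −0.34 and interferon response genes at 0.32.

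Genes in the first 20 Mb of chromosome 10 were higher in KO libraries, with a median log2 fold change of 0.30 over 61 genes (camera adjusted p = 3.1e-05). With the estimated correlation of −0.00709 camera did not call the region (adjusted p = 0.746). That estimate lies below the preset 0.01, and the same setting missed the simulated shift, so the lost call cannot decide. Of 169 chromosomes and 20 Mb bins tested, 4 were called as higher and 7 as lower with the preset correlation, and 0 with an estimated correlation. The other higher bins lay on chromosome 4 (49 genes, 0.17) and chromosome 13 (70 genes, 0.16; 28 genes, 0.15). The lower sets were the mitochondrial genome (17 genes, −0.43), the last bin of chromosome 17 (21 genes, −0.35), chromosome 19 as a whole (480 genes, −0.12) and its first 20 Mb (163 genes, −0.18), and 3 bins of chromosome X (80, 51 and 36 genes, at −0.18, −0.13 and −0.18). All sets included pseudogenes, and they were not tested with pseudogenes removed. The X bin of 51 genes holds the called pseudogenes RPS23P8 (−1.32) and RPS26P11 (−5.51), named after their values were seen. How far lower pseudogenes contribute to the lower sets was not tested. The number of sets called was 4 without WT replicate 1, 9 without WT replicate 2, 4 without KO replicate 1 and 7 without KO replicate 2, and the region of chromosome 10, the last bin of chromosome 17 and the first 20 Mb of chromosome 19 passed in each of these. The median difference in log2 CPM of the mitochondrial genome went from −0.42 to −0.20 without WT replicate 2 (camera adjusted p = 0.410) and −0.22 without KO replicate 2 (0.452), and that of the X bin of 80 genes from −0.17 to −0.09 without WT replicate 1 (0.400) and −0.12 without KO replicate 1 (0.381). The other 6 sets each lost their call without 2 or more of the libraries and kept their direction. Over the fits without 1 library, their medians in log2 CPM ran from 0.16 to 0.21 in the chromosome 4 bin. In the chromosome 13 bins of 70 and 28 genes they ran from 0.14 to 0.20 and from 0.16 to 0.23. For chromosome 19 the range was −0.16 to −0.11, and for the X bins of 51 and 36 genes −0.21 to −0.13 and −0.31 to −0.12. The log2 fold change correlated with GC content across 8483 protein-coding genes (Spearman rho of −0.16, with genes not independent replicates). Once a GC and length trend was removed, an alternative chosen after seeing the data, the calls of 8 sets ended. The shift became smaller in chromosome 19 (median difference in log2 CPM −0.12 before and −0.07 after; camera adjusted p = 0.191), its first 20 Mb (−0.18 and −0.08; 0.197), and the mitochondrial genome (−0.42 and −0.29; 0.161). It stayed about as large in the bins of chromosome 13 (0.16 and 0.15; 0.15 and 0.16; both 0.161), chromosome 4 (0.17 and 0.14; 0.123) and the X bins of 80 genes (−0.17 and −0.16; 0.0880) and 36 genes (−0.18 and −0.15; 0.161), although the calls were lost. The last bin of chromosome 17 stayed called with a smaller median (−0.29 and −0.14; 0.0448), as did the X bin of 51 genes (−0.12 and −0.12; 0.0448) and the region of chromosome 10 (0.28 and 0.28; 7.5e-05), and a bin of chromosome 3 with 34 genes was called in addition (0.0448).

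The authors' deposited table lists 4 genes as higher and 30 as lower in KO cells at an adjusted p under 0.05. It gives DDR2 a log2 fold change of 2.99, IGF2R one of −5.03 and FHL1 one of −1.97 in the authors' deposited table, and HEMK1 one of −1.16 with an adjusted p of 1.00. Of those 34 genes 28 were also called by edgeR here, and 10604 of 10669 genes with a fold change in both had the same sign (99.4%). DESeq2 applied here to the deposited counts called the same 34 genes, with a median absolute difference from the authors' deposited log2 fold changes of 1.2e-05.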

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

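Removal of pseudogenes and of the GC and length trend was chosen after seeing the data; the other alternatives were fixed before. Counts of 5 higher and 30 lower genes stayed within 1.5 times under both other scalings, DESeq2, limma-voom and removal of mitochondrial genes, where they lay between 4 and 5 and between 28 and 37. Without a count filter 31 genes were higher and 125 lower, at least 1 CPM in 2 libraries gave 47 lower, a 1.5-fold threshold 16 lower, removal of pseudogenes 10 lower and removal of the GC and length trend 9 higher; the cause was not tested except that fewer genes enter without pseudogenes. Leaving out each library gave 1 (without WT replicate 2) to 25 (without KO replicate 2) higher and 3 (without WT replicate 1) to 164 (without KO replicate 2) lower genes, with the lone library of a group assumed to vary like the other group. DDR2 passed in all 15 alternatives (highest adjusted p = 0.0360); limma-voom lost IGF2R (−4.91; 0.0806) and LINC00115 (−3.82; 0.115), and the 1.5-fold threshold lost SRSF5 (0.590), NF2 (0.322), LINC00115 (0.0677) and SOX11 (0.0561), as it tests the same folds against a larger change.

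With the same replicate number as a block, 29 genes were higher and 111 lower; 0 lists were called, and the mitochondrial mRNAs (mean −0.35) had an adjusted p of 0.0553. The numbers do not pair the libraries in the labels, and the deviations of same-numbered libraries correlated at −0.0351. Some alternatives also added calls over all genes. RPL26 (edgeR adjusted p = 0.0617 in the main fit) passed with DESeq2 size factors (0.0479) and at least 1 CPM in 2 libraries (0.0292). MKI67 (0.0814) passed without a count filter (4.9e-05) and with the block (3.4e-05). Neither gene passed with upper-quartile scaling, DESeq2 or limma-voom.

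The mean of the mitochondrial mRNAs was −0.35 with an estimated correlation (adjusted p = 0.881), −0.37 with at least 1 CPM in 2 libraries (0.108), −0.23 after removal of the GC and length trend (0.317), and between −0.56 (without KO replicate 1) and −0.15 (without KO replicate 2), with −0.21 without WT replicate 2 and −0.51 without WT replicate 1; adjusted p over all alternatives ran from 0.00275 to 0.881. Against 2 lists called, 0 were called with an estimated correlation, with at least 1 CPM in 2 libraries and by fry in 1 direction, 1 after removal of the trend, and 1 to 2 without each library, where they were the mitochondrial mRNAs without either first replicate, and otherwise lists not called with all libraries. Against 11 chromosome sets called, 0 were called with an estimated correlation, 6 with at least 1 CPM in 2 libraries, 4 after removal of the trend, and 4 to 9 without each library. HEMK1 stayed below 0 and uncalled in all 8 alternatives, from −2.91 without KO replicate 2 to −0.36 without KO replicate 1. At 15 counts in WT and 8 in KO libraries a difference in HEMK1 was not detectable.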

Other observations

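Transcripts of blood cells appeared at a very low level in the KO libraries. Lysozyme (LYZ) had 13 counts in KO replicate 2 and 0 in each of the other 3 libraries, and haemoglobin beta (HBB) had 4 and 11 counts in the KO libraries and 0 in both WT libraries. The 11 markers of other human lines, HeLa or keratinocyte type, summed to 40.8 and 43.0 CPM in WT and 38.2 and 44.0 CPM in KO libraries. Kidney and embryonic renal markers summed to 44.8 and 47.9 CPM in WT and to 38.9 and 41.8 CPM in KO libraries.

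Of the tests below, those of the parents' RNA, of the mitochondrial mRNAs without WT replicate 2 and of nuclear copies of mitochondrial DNA were chosen after their result was seen, and the others before.

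Processed pseudogenes were lower in the KO libraries, and lower RNA of their parent genes is argued against by a median log2 fold change of 0.0140 in 170 parents. GC content or length is argued against as the whole cause, since the pseudogenes lay −0.40 (95% bootstrap interval −0.46 to −0.35) from coding genes matched on GC content, length and abundance. A candidate explanation is that reads shared with near-identical genes were placed differently in the 2 groups: 192 pseudogenes of nuclear, non-ribosomal parents lay −0.45 (−0.52 to −0.38) from their parents. That test does not separate placement of reads from a change in RNA of the pseudogenes themselves, the medians did not deepen with identity to the parent (−0.59 at 90 to 95% and −0.50 over 98%), and an effect of the KO stays open, as untested. WT replicate 1 carries much of the size, with pair medians of −0.91 and −0.69 against it and −0.34 and −0.09 against WT replicate 2. The median of WT replicate 2 against WT replicate 1 was itself −0.51, a spread that the intervals above do not cover.

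Genes of the first 20 Mb of chromosome 10 were higher in the KO libraries, and GC content or length is argued against by a median of 0.28 (95% bootstrap interval 0.20 to 0.41) over 61 genes once that trend was removed. No single library carried the shift in these data, as 4 of the 4 pairs of a KO and a WT library had a median above 0.15. These pairs share libraries, and the region was picked for its shift in them. The count of pairs therefore cannot show whether the shift would recur in other libraries. An extra copy of the region in the KO clone and a regional change of transcription cannot be told apart: 86.9% of the genes lay above 0 (exact 95% interval 75.8 to 94.2%), but the region was picked out of 169 sets for its shift, so this share restates the choice and speaks for neither. The medians over 10 Mb windows were 0.25 and 0.30 in the region, 0.12, 0.10 and 0.17 in the next 3 windows, and between 0.00249 and 0.14 in the other 9. DNA copy number was not analysed here.

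The mRNAs of mitochondrial DNA were lower in the KO libraries, and a move of reads to nuclear copies is argued against, since the share of counts in such copies also differed by −0.0415 percentage points (KO minus WT). A candidate explanation is that single libraries carry the shift: the mean of −0.35 was −0.21 without WT replicate 2 and −0.15 without KO replicate 2, and WT replicate 1 and KO replicate 1 had shares of 2.50% each. Without either first replicate the mean was further from 0, reaching −0.56 without KO replicate 1. An effect of HEMK1 loss on these mRNAs stays open, as untested apart from the libraries' spread.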
